A study of Homo sapiens with 2 samples.

How the data were processed

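The series measured RNA from exosomes, the small vesicles that cells release, in medium conditioned by SW480, an established human colorectal cancer cell line. Its title gives natural antisense transcripts, RNAs copied from the strand opposite a gene, as its subject. Per the labels' protocols, cells were grown for 72 h, washed and kept in serum-free medium for 48 h. The medium was cleared by 3 centrifugation steps, at 300, 2000 and 12000 times gravity, passed through a 0.22 µm filter and ultracentrifuged at 120000 times gravity for 70 min, with a wash and a repeat of that last spin. Per the labels' protocols, 1 ng of RNA was amplified with the Ovation Pico WTA V2 whole-transcriptome kit, and the amplified DNA was labelled with Cy3 by an enzymatic kit made for genomic DNA. Each sample was hybridised in a single colour.

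The deposited table holds 1 intensity per feature and array, on a linear scale, for 45220 features numbered from 1 to 45220. The authors gave no unit in the table. That the values are linear spot intensities was read from the values themselves, which ran from 4.86 to 621000 and held no value at or below 0. The values are rounded to 3 significant digits. Agilent Feature Extraction 8.1 is listed, with no role, in the submitters' processing notes. How background was subtracted, how dim spots were replaced and whether any scaling was applied are not given in the sources used here. The columns were not centred on each other and were not scaled to one median or 75th percentile, because their medians and 75th percentiles differed. The highest values lay above 65535, the ceiling of a 16-bit scan, so the deposited values cannot be unscaled readings of a single 16-bit image.

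Features are identified by number only, and no table used here pairs those numbers with probes, sequences, strands or genes. The gene table supplied for human genes has 0 columns of probe or feature identifiers. Sense and antisense probes, control spots and genes therefore could not be told apart, and all features were kept. The planned comparison of probe classes, the planned pairing of sense and antisense probes and the 17 gene lists fixed before the data were examined could not be run. No transcript was named.

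The 2 samples form 1 group, so no comparison between conditions exists and no test of a difference between conditions was made. The labels call the samples replicates and do not say whether they came from separate cultures, so the spread between them may be technical. Intensities were used as deposited, after log2 transformation, with no pseudocount, background correction or normalization. Agreement was measured across features by Pearson's r, Spearman's rho and the SD of the log2 difference. No p-value was attached, since features are not independent replicates. Features were counted as above the floor when they exceeded the array's median, because negative-control spots could not be identified. That floor is a rank and not a detection limit. Differences were counted past 1 log2 unit, which is 2-fold. The precision of an array depends on the number of arrays, here 2, and no counting interval applies.

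The rule for single features, fixed before the data were examined, took the 20 highest mean log2 signals and the features with the largest difference in each direction among those above the floor on both arrays. Because features are unnamed, the 20 are described as a set. Only 2 features in each direction were taken, fewer than the rule had planned. Spots of different sequence bind with different strength, so a bright spot is not a measure of an abundant transcript and no feature's level was set against another's.

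The alternatives fixed before the data were examined were scaling to a common 75th percentile, quantile normalization, stricter floors, a low-value floor at the 20th percentile, and each array alone. Those added afterwards were the edge of a low-signal plateau as a floor (6.4 intensity units), removal of a position trend, and omission of the brightest features. An alternative was called moved when r, rho or the SD left the 95% interval of 200 bootstrap draws over features, or when a count changed by over 1.5 times. That interval is narrow with 45220 features and does not measure the spread between arrays, so small changes can count as moved. The log2 difference of a single feature was called moved when it changed by more than the SD of its 2 values, and the mean of the 20 brightest features when it changed by more than their mean SD between arrays. Some values could not move by construction. Scaling to a 75th percentile shifts all log2 differences by one constant, so r, rho and the SD stay fixed. It took the median log2 difference from 0.03 to -0.03, too small a change to move or reverse a named feature. Quantile normalization keeps ranks, so rho and the count above the median stay fixed. The count above the median of 1 array alone is set by that median. The counting of differences was tested on simulated arrays of 45220 features with the measured means. The simulated differences were normal, with a spread set in each of 10 groups by signal from the median absolute deviation. Such noise leaves out the extreme differences of the real arrays, so the shares found may be too favourable. It found 100% of 100 features raised by 1.5 log2 units and 100% of 100 features lowered by 2 log2 units, all with signals over 100, where the spread is far below these shifts. In features with signals from 10 to 50, the same shifts were found for 84% and 100% of 100 features each, and 509 of 9038 unchanged features (5.63%) also passed 1 log2 unit. The lowest signals, on and next to the plateau, were not part of these simulated shifts. The fit of position was tested on 12848 features with a simulated trend that held 39.2% of the variance, and recovered 39.3%. The simulated trend had the form that was fitted, so this checks the calculation and not whether a real trend has that form. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.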

Results

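RNA from the exosomes of SW480 colorectal cancer cells was profiled on 2 single-colour arrays, labelled replicates 1 and 2. The arrays carried 45220 features each. The samples analysed here include no untreated, cellular or other control, so the measurements address how much signal exosomal RNA gave on this array and how closely the replicates matched. Which features report antisense transcripts, sense transcripts or controls is not given in the sources used here, and the groups described below are groups of features by signal.

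Signal covered the same wide range on both arrays. Intensities ran from 4.86 to 621000 in replicate 1 and from 5.01 to 592000 in replicate 2. The medians were 23.9 and 25.3, the 75th percentiles 132 and 138, and the 90th percentiles 572 and 592, in replicates 1 and 2 respectively. The median difference, replicate 2 minus replicate 1, was 0.03 on the log2 scale over all features. The summed signal was 1.414e+08 in replicate 1 and 1.406e+08 in replicate 2.

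The features were described in 3 sets by signal, with edges placed after the distribution had been seen. The dimmest set formed a narrow plateau below 6.4 intensity units, which held 13106 features (29.0%) in replicate 1 and 12648 features (28.0%) in replicate 2. The plateau's level drifted along the feature numbers. Its median fell from 5.90 in the first 10% of features to 4.99 in the last 10% in replicate 1, and from 5.68 to 5.16 in replicate 2. Membership was shared for 10646 features, against 3666 if the arrays were independent. Arrays that carry the same features are not independent, so this excess does not show shared RNA content. No order among transcripts was read from values on the plateau.

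Above the plateau lay a broad distribution. Signals between 6.4 and 20 were held by 8224 features in replicate 1 and 8262 in replicate 2. Signals between 20 and 100 were held by 10834 and 11058 features, and those between 100 and 1000 by 10070 and 10175. A further 2336 features in replicate 1 and 2410 in replicate 2 lay between 1000 and 10000, and 308 and 325 features lay above that but under the brightest set. In all, 30112 features (66.6%) were above the plateau on both arrays, compared with 51.2% if membership were independent. That excess likewise does not show shared RNA content.

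The brightest set was separated from the rest by an empty interval. In replicate 1 no feature lay between 120000 and 146000, and in replicate 2 none lay between 119000 and 146000. The same 342 features (0.756% of the array) lay above that gap on both arrays. Their median intensity was 329500 in replicate 1 and 332500 in replicate 2, and they carried 85.3% and 84.8% of the summed signal. The log2 difference between arrays had an SD of 0.06 over these features and a median of -0.01. The probes of these features are not identified here. Counts did not fall steadily towards the gap. From log2 15.5 to 16 there were 20 features in replicate 1 and 19 in replicate 2. From log2 16 to 16.5 there were 31 and 34. Features above 65535 numbered 396 and 398, so some of them lay under the gap.

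**Figure D1:**
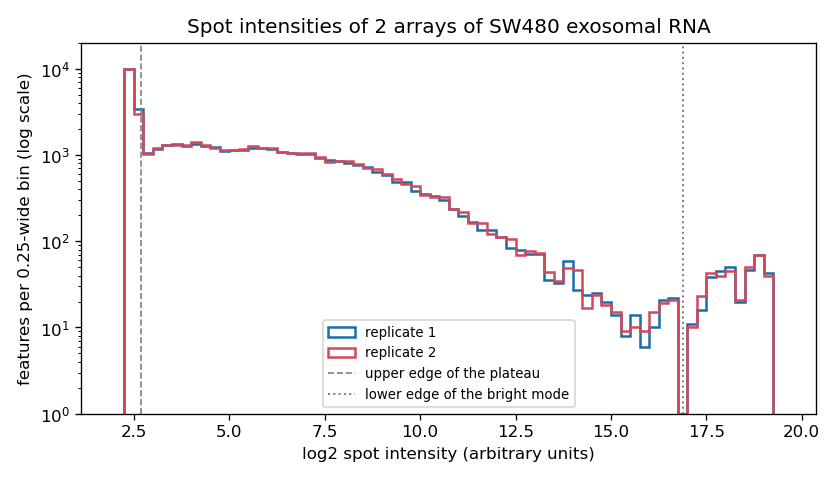
Number of features (log-scaled vertical axis, bins 0.25 wide) by log2 spot intensity in arbitrary units for replicate 1 (blue) and replicate 2 (red) of SW480 exosomal RNA. The peak left of the dashed line is the plateau of 13106 and 12648 features, and the group right of the dotted line is the set of 342 features shared by both arrays.

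Correlation between the replicates was higher above the plateau than within it, where the range of values is narrow. Across all 45220 features the log2 intensities gave Pearson's r = 0.989 and Spearman's rho = 0.957, and the log2 difference had an SD of 0.43. Among the 30112 features above the plateau on both arrays, r was 0.992 and rho was 0.985. Within the shared plateau, r was 0.59 and rho was 0.63. A narrow range by itself lowers r and rho, so the lower values do not show poorer agreement on the plateau. These correlations are across features, which are not independent replicates. The features above the array's median numbered 22590 in replicate 1 and 22589 in replicate 2, and 21696 of them (48.0% of the array) were above it on both, where independent arrays would share 24.95%. The brightest 10% shared 4444 features, against 452 expected from independent arrays. Both arrays carry the same features, and spots of different sequence bind with different strength. Sharing above independence and a high r can therefore arise even between unlike RNA samples, and none was available for comparison. With 1 pair of samples, it cannot be judged whether replicates of separate cultures would match less closely.

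The spread between arrays depended on signal. Among the features ranked by mean log2 signal and divided into 10 equal groups, the fourth group had the widest spread, with an SD of 0.96 around a median signal of 9.71. There 1660 features (36.7%) differed by over 1 log2 unit. The SD was 0.37 at a median signal of 33.6, 0.21 at 65.9, 0.14 at 135 and 0.08 in the brightest group, at a median signal of 1469. In that brightest group 95% of log2 differences lay between -0.10 and 0.21. The 2 dimmest groups, which lie in the plateau, had SDs of 0.06 and 0.07. Their narrow spread is partly set by the ranking, which used the mean of the same 2 values. A feature on the plateau on one array and well above it on the other falls into a middle group. Of the 13158 features with a mean signal of 100 or more, 97.1% agreed within 1.2-fold.

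A total of 2333 features (5.16%) differed by over 1 log2 unit, 1314 higher in replicate 2 and 1019 higher in replicate 1. This split of 56.3% to the side of replicate 2 became 49.5% when the arrays were scaled to a common 75th percentile. In 1530 of the 2333 features (65.6%), the feature was on the plateau on one array and above it on the other. Of the features above the array median on both arrays, 23 differed by over 1 log2 unit, 12 of them higher in replicate 1 and 11 higher in replicate 2.

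**Figure D2:**
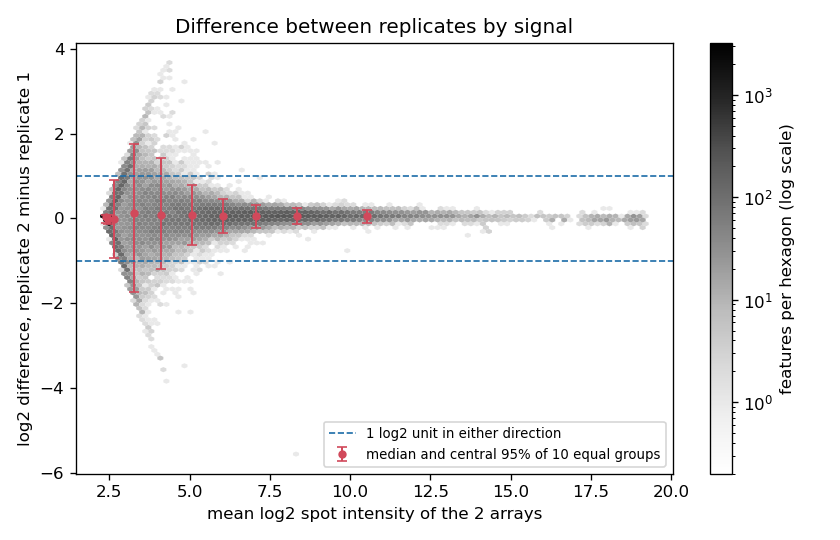
Log2 difference (replicate 2 minus replicate 1) of each feature against its mean log2 intensity, with darker hexagons holding more features and dashed lines at 1 log2 unit. Red points are medians of 10 equal groups by signal and bars span the central 95% of features. The SD falls from 0.96 in the fourth group to 0.08 in the brightest group.

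Single features stood out from this spread. Feature 34492 read 2210 in replicate 1 and 46.9 in replicate 2, which was 47.1-fold lower in replicate 2 (mean 1128 ± 1530, SD, n = 2). Feature 28297 read 94.7 in replicate 1 and 38.9 in replicate 2, a log2 difference of -1.28. In the opposite direction, feature 12961 read 28.6 in replicate 1 and 98.3 in replicate 2, a log2 difference of 1.78. Next came feature 12791, at 36.6 in replicate 1 and 94.1 in replicate 2, a log2 difference of 1.36. Only 1 other feature besides feature 34492 had a mean signal of 100 or more and differed by over 1 log2 unit. That was feature 11452, with 70.0 in replicate 1 and 154 in replicate 2 (mean 112 ± 59.4, SD, n = 2), and it was chosen after its values were seen. With 1 sample on each side, none of these differences could be tested.

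The 20 features with the highest mean signal all belonged to the 342 unidentified features above the gap. That they lay in the brightest 10% of both arrays therefore follows from how they were chosen. Their intensities ran from 561000 to 621000 in replicate 1 and from 528000 to 592000 in replicate 2. No feature of the 20 differed by more than 1.13-fold between the arrays. When each array was ranked alone, 18 of the 20 remained among the 20 brightest in replicate 1 and 13 in replicate 2.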

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

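Of 59 recomputed values, 17 moved and 42 stayed within the stated limits, some of these by construction. Settings on the plateau, position and the brightest features were chosen after seeing the data. Agreement was higher among features that passed a cut on both arrays. Such a cut removes dim features and also those on opposite sides of it. Part of the rise, and of the fall in counts, is therefore by construction. Among features above the median on both arrays r was 0.997, rho 0.993 and the SD of the log2 difference 0.18, and the counts past 1 log2 unit were 11 and 12 (higher in replicates 2 and 1). Above the plateau on both arrays r was 0.992, rho 0.985 and the SD 0.35, with counts of 494 and 309. That cut took out the 1530 features past 1 log2 unit that were on the plateau on one array only. With low values raised to the 20th percentile, r was 0.990, rho 0.959 and the SD 0.42. Without the brightest set r was 0.987, and with the position trend removed rho was 0.962. Fewer features by construction exceeded a floor at the 75th percentile (11076) or the 90th (4444). Neither scaling to the 75th percentile nor quantile normalization moved a value, partly by construction. With them, and with the position trend removed, slightly more features were higher in replicate 1 than in replicate 2. The removed trend included a constant, and it took the median log2 difference from 0.03 to -0.03, as scaling to the 75th percentile did. Its effect on this split is therefore not separate from scaling. The features named by number kept their direction under both scalings and with the position trend removed. Each of these settings changed the log2 differences too little to move or reverse any of them, so this is no separate support. Leaving out an array leaves no difference to compute. Alternatives for probe classes, gene lists and sense-antisense pairs were not run, since the features are unnamed. No paired analysis was possible because there is 1 group. Values on the plateau were correlated between arrays, but the plateau's level fell along the feature numbers on both. A drift shared by the arrays can give a correlation without shared RNA signal, and it was not removed before r was computed. Without negative-control spots, these arrays also do not show whether a feature there has signal above background.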

Other observations

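All tests in this part were chosen after the results they bear on were seen, and with a single group no biological explanation was tested. The 342 features above the gap held most of the signal on both arrays, and their nature decides what a sum of signal means. One candidate explanation is a few probes printed in many copies, as array makers do with control probes. Copies of one probe should give narrow clumps of intensity, and the log2 intensities were clumped: in bins 0.1 wide, the lower of the arrays' chi-squares against a smoothed density was 99.0, above the highest of 1000 draws from that density on either array (49.6). Saturation of the whole set at one ceiling value is argued against. The set ran from 146000 to 621000 in replicate 1 and from 146000 to 592000 in replicate 2. At most 0.877% of it lay within 1% of an array's highest value. That window is narrow beside the SD of 0.06 log2 units between arrays, so saturation of part of the set is not excluded. Whether the probes are controls or report an abundant RNA, such as ribosomal RNA, stays open until the features are identified.

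Features that differed by over 1 log2 unit were nearly all dim. Measurement noise near background would place them there, and 0.0857% of the 2333 had a mean signal of 100 or more, while 29.1% of all features did. That share restates where the differences lay, so it is no separate test of noise. Of the 10 groups by signal, the 2 dimmest, in the plateau, held 0 of them each, and the fourth held 1660. The values of 0 follow from the grouping. With minima of 4.86 and 5.01 in replicates 1 and 2, a feature with so low a mean cannot differ 2-fold. The count in the fourth group is also partly made by ranking on the mean of both arrays. Dim features of this table may still be unsuited to any count of transcripts present in 1 replicate and missing from the other. The exceptions were feature 11452, at 70.0 and 154, and feature 34492, which differed far more, at 2210 and 46.9. For feature 34492, a blemish covering neighbouring spots is argued against, since the median absolute log2 difference of its 8 neighbours was 0.0574, below the 75th percentile of 0.169 around 2000 other features. A defect of that spot alone and a real difference in the sample cannot be separated with these arrays, and neither was tested.

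Small differences between bright features followed the feature numbers. The numbers suggest rows of 85 features, because signal on both arrays resembled itself most at a distance of 85 among 1000 distances, though the autocorrelations were only 0.03 and 0.04. With that layout, a quadratic surface in row and column explained 13.3% of the variance of the log2 difference among 17259 features above 50 on both arrays, against at most 0.117% in 1000 shuffles of position. Median differences ranged from -0.01 to 0.10 across 10 bands of columns. Spot position on the slide therefore fits part of the residual difference, and removing the surface lowered its SD from 0.126 to 0.117. The remaining spread is not explained by this surface.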
